A study of Mus musculus with 13 samples.

How the data were processed

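Bulk RNA sequencing libraries from 13 mouse hippocampi were analysed, 7 from App NL-G-F mice with floxed Lpcat3 and vav1-Cre and 6 from App NL-G-F mice with floxed Lpcat3 alone. Per the labels' protocols, total RNA was extracted with a column kit, its quality was read on a TapeStation, and libraries were made with the SMART-Seq mRNA LP kit, which primes on poly(A) tails and amplifies the cDNA by PCR. The labels give male mice at 9 months and, for every sample, gavage with tamoxifen at 20 mg/ml and 0.2 mg per g body weight; they do not say whether deletion depended on it. The submitters' processing notes name STAR 2.7.10a, featureCounts 2.0.3, R 4.2.0, DESeq2 1.36.0 and the genome build GRCm39, without the role of each. The annotation release, strand setting and treatment of multimapped reads are not given in the sources used here. Reads of overlapping or antisense genes, and of families with near-identical copies such as ribosomal protein, H2, Ifit and Gbp genes, are therefore uncertain.

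The deposited file is a table of whole-number read counts per gene, 56980 Ensembl genes in 13 columns, not normalized, and each column was matched to its sample by the number in the sample's title. Totals ran from 12159941 to 18322559 counts per library and did not differ between groups (exact two-sided permutation p = 0.46). Gene symbols were matched by Ensembl identifier for 52073 genes, which held 99.7% of the counts. The only annotation at hand was GENCODE M21 on GRCm38, an older build, so no coordinates are given; chromosome, exon length and GC content were taken from it, with a value for 98.5% of the genes tested. No 2 libraries of a group agreed within sampling noise (chi-square per gene of 3.50 to 26.8 over 36 pairs), so all 13 were kept.

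Groups were compared with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, TMM factors, filterByExpr by group, no covariates), with Benjamini-Hochberg adjustment over 17549 genes and a threshold of 0.05. CPM values given as means ± SD were computed from the deposited counts with TMM factors. Summed CPM of lists below the filter were instead scaled by library size alone. The 43 gene lists (microglial states, immune pathways, lipid and phospholipid pathways, neural, vascular and regional cell markers, stress and housekeeping genes) were fixed before the data were examined; 38 had at least 5 genes after the filter and the other 5 are given as summed CPM. Each list was tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. A list's score is the mean log2 CPM (prior count 2) over its filtered genes in each library. The septum and striatum scores of the closing section instead used unfiltered genes, scaled by library size alone. Score differences were tested with exact two-sided permutation over all 1716 splits of the 13 libraries, with a smallest possible p of 5.8e-04. Members of a list were also adjusted over the list alone.

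Genes were named by a rule fixed before the data were examined. It took a panel of 20 genes whatever their result, the genes past the threshold (up to 10 per direction, predicted genes excluded) with up to 5 per direction that did not pass, and up to 2 members per list with the smallest adjusted p among those past 0.05 over all genes or over the list. Other genes named as examples within a list, and the region markers in the closing section, were chosen after their values were seen. Gm37068 falls outside the rule as a predicted gene and was likewise chosen after its values were seen. No number is shared between the groups in the labels, so no pairing was fitted.

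The labels' sample numbers fall into 3 runs (3283 to 3288, 3296 to 3300 and 4301 to 4307); what the runs stand for is not stated, and they were used as a fit term and as strata of a permutation with 72 relabellings, whose smallest p is 0.014. Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom with quality weights, robust edgeR, other scaling factors, no count filter, a mean count of at least 50, run terms, covariates for choroid plexus, myelin and homeostatic microglia, gene counts without samples 4301 to 4307, the median in place of the mean of a list, and leaving out each library. Alternatives chosen after seeing the data were leaving out each library for the type I interferon score, removal of length and GC trends per library (lowess, span 0.4), a septum marker covariate, and list tests and list scores without samples 4301 to 4307. Other scalings moved the median log2 fold change of all genes from -0.004 to between -0.014 and 0.004.

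The analysis was tested on simulated counts for 17352 genes with the real library sizes and 200 changed genes. In the knockout against control design edgeR recovered 40% of genes changed 1.25-fold, 64% at 1.5-fold, 92% at 2-fold and 100% at 3-fold, with 2.65% false calls. The simulated genes varied independently, unlike the real ones, so these rates need not hold for the real data. PCR copies are not independent molecules, so counting floors (3 reads over a group) cover counting error only. Because Cre was present only in the knockout group, effects of Cre and of Lpcat3 deletion are not separated by this design.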

Results

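RNA was sequenced in bulk from 13 hippocampi of male mice aged 9 months. All carried the App NL-G-F allele, a knock-in of the amyloid precursor protein gene with familial Alzheimer's disease mutations, which leads to amyloid plaques without overexpression of App. All were also homozygous for a floxed Lpcat3 gene. In 7 samples the vav1-Cre transgene, which is active in blood-forming cells and their descendants, was present, and these form the knockout group. The other 6 had the floxed gene without Cre and form the control group, which the labels call wild type. The deposited table held 12159941 to 18322559 counted reads per sample, with a mean of 14261564 ± 1427460 (SD, n = 6) in controls and 15119972 ± 2178491 (SD, n = 7) in knockouts. The labels do not state that each sample was a separate animal, so p-values measure the spread between these samples.

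The comparison asks how deletion of Lpcat3, the enzyme that places arachidonic acid into membrane phospholipids, alters the microglial response to amyloid. Because whole hippocampus was sequenced, microglia supplied only part of the RNA. Lpcat3 (ENSMUSG00000004270, chromosome 6 in GENCODE M21) was at 27.6 ± 2.22 CPM (SD, n = 6) in controls and 20.2 ± 2.83 CPM (SD, n = 7) in knockouts. The groups did not overlap, with controls between 24.7 and 30.3 CPM and knockouts between 17.3 and 24.3 CPM (exact two-sided permutation p = 0.0023 over 1716 splits). The log2 fold change was -0.45 (SE 0.088). Its adjusted p over all genes was 0.096 in edgeR's quasi-likelihood test and 0.0020 in DESeq2, and it ranked at place 9 among 17549 genes tested. In edgeR it also passed when control replicate 1 (adjusted p = 0.034) or knockout replicate 3 (adjusted p = 0.028) was left out. Within the 3 runs of label numbers described further on, Lpcat3 differed by -0.36, -0.24 and -0.46 in mean log2 CPM, and with the runs as a term its log2 fold change was -0.35 (adjusted p = 0.49 in edgeR). App itself was at 1263 ± 61.8 CPM (SD, n = 6) in controls and 1307 ± 23.7 CPM (SD, n = 7) in knockouts, with an adjusted p of 0.65 in edgeR.

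Few genes changed singly. Gm37068, Kcp and Sva were higher in the knockout and Meis2 was lower at an adjusted p under 0.05 in edgeR. An unadjusted p under 0.05 was held by 2189 genes, 917 higher and 1272 lower in the knockout. Chance would give 877 on average, but genes vary together and chance counts spread widely. Of 100 splits of the libraries, 2, the real one included, gave as many. The other splits had a median of 729 and reached 2235. With the run term 1501 genes had an unadjusted p under 0.05. Meis2 (ENSMUSG00000027210), a homeobox transcription factor, fell from 70.4 ± 5.55 (SD, n = 6) to 54.4 ± 3.94 CPM (SD, n = 7), a log2 fold change of -0.37 (SE 0.059) with an adjusted p of 0.022 in edgeR. Next among the higher genes, without passing, were Banp (log2 fold change 0.60), Smarcd2 (0.36), Ippk (0.29), Zswim5 (0.33) and Nptx2 (0.47). Next among the lower were Cmtm5 (-0.30), Gstm5 (-0.30), Xkrx (-1.24) and Prdx1 (-0.26), with adjusted p between 0.075 and 0.097 for all of these and for Lpcat3 in edgeR. The counts depended on the tool and on 1 library: DESeq2 called 104 genes higher and 100 lower, and edgeR called 40 higher and 40 lower without control replicate 1. Meis2 was no longer called in edgeR without any one of knockout replicates 2, 4, 5, 6 and 7 or control replicates 3, 4 and 5, with adjusted p between 0.018 and 0.119 over all 13 omissions. Nor was it called at a mean count of 50 or more (adjusted p = 0.064), with the run term (0.41), without samples 4301 to 4307 (0.066), or with the myelin (0.094) or septum (0.18) score as a covariate; the Meis2 log2 fold change there lay between -0.38 and -0.31.

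Gm37068 and Sva had no read in any control and were counted in all 7 knockouts. Gm37068, a predicted gene on chromosome 1 in GENCODE M21 chosen after its values were seen, had 36 to 63 reads per knockout. With a floor of 3 reads over all 6 controls together this is at least 101-fold higher. Sva (seminal vesicle antigen, ENSMUSG00000023289, chromosome 6) had 17 to 26 reads per knockout, at least 45.0-fold higher by the same floor. No other gene was absent from all controls with 10 or more reads in every knockout, and no gene was distributed the opposite way. Kcp (kielin/chordin-like protein, ENSMUSG00000059022, chromosome 6) rose from 2.26 ± 0.37 (SD, n = 6) to 7.45 ± 0.86 CPM (SD, n = 7), a log2 fold change of 1.71 (SE 0.13, adjusted p = 5.0e-07 in edgeR), and the groups did not overlap.

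**Figure D1:**
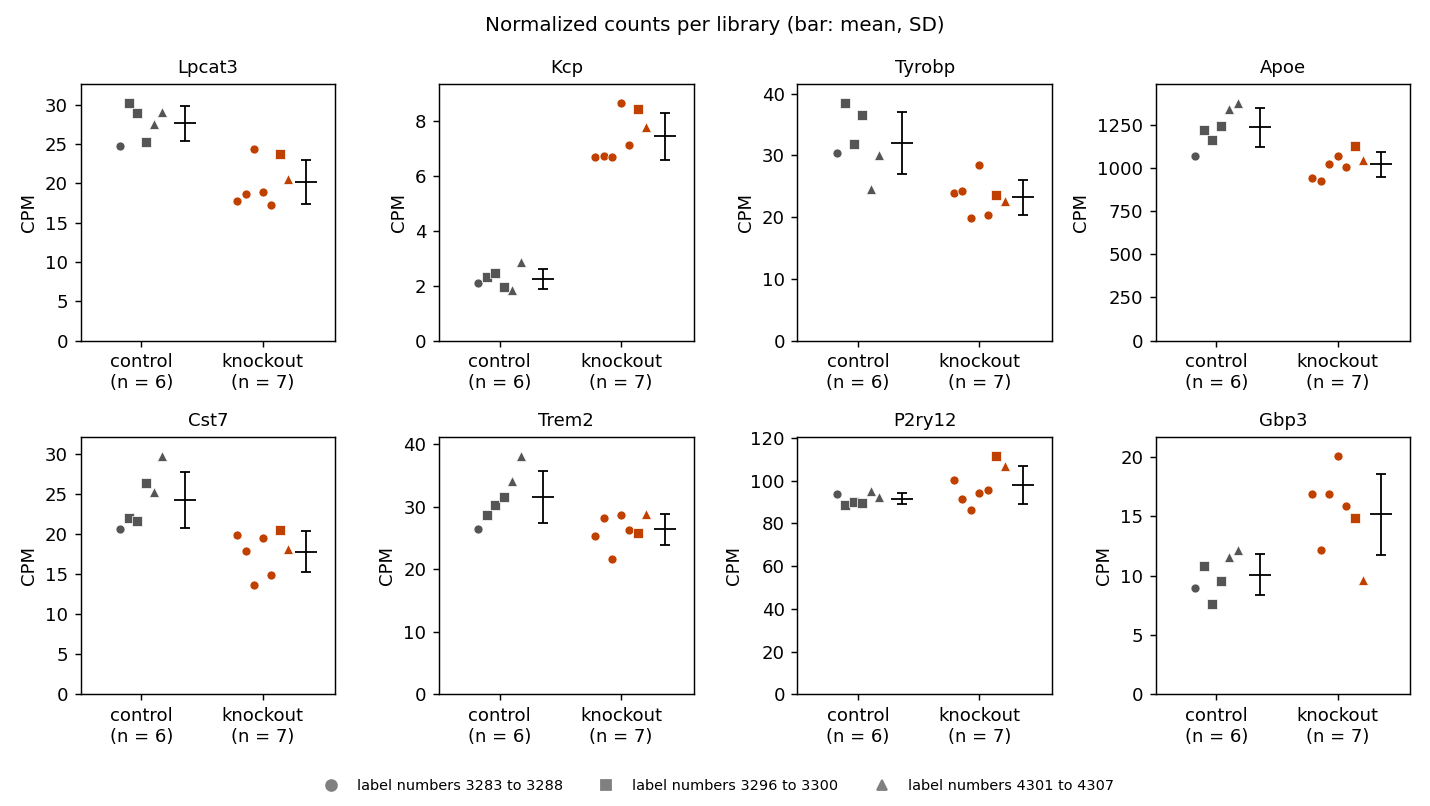
Normalized counts (CPM, vertical axes from 0) of 8 genes in each control and knockout library; symbols give the run of label numbers and the bar the mean with its SD. Lpcat3 and Cst7 were lower and Kcp higher in every knockout than in every control, whereas the groups overlapped for Tyrobp, Apoe, Trem2, P2ry12 and Gbp3.

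Genes of disease-associated microglia, the state that microglia take around amyloid plaques, were lower in the knockout, while homeostatic microglial genes were not. Of 34 disease-associated genes, 10 fell when p was adjusted over the list alone, 0 rose and 24 did not pass; 0 passed over all genes tested, while 29 of the 34 had negative values. The 10 were Tyrobp, Ccl6, Apoe, Cst7, Igf1, Cd68, Clec7a, Itgax, Trem2 and Ctsz. Tyrobp, the signalling adaptor of Trem2, fell from 31.9 ± 5.01 to 23.2 ± 2.83 CPM (log2 fold change -0.46, SE 0.099). Apoe, the lipid carrier also made by astrocytes, fell from 1235 ± 114 to 1020 ± 70.7 CPM (-0.27, SE 0.060). Cst7, a cysteine protease inhibitor, fell from 24.3 ± 3.48 to 17.8 ± 2.57 CPM (-0.45, SE 0.11), and Trem2, the lipid-sensing receptor, from 31.5 ± 4.14 to 26.4 ± 2.55 CPM (-0.26, SE 0.085); these are means ± SD with n = 6 and 7. The chemokine gene Ccl6 (-0.47), Itgax (-0.33) and Clec7a (-0.27) fell as well. Short genes were lower in the knockout in general (69.5% of the shortest 20% of genes by exon length against 47.0% of the longest 20%). With the length and GC trends removed, 8 of the 34 still fell when adjusted over the list alone; Tyrobp moved to -0.26 (SE 0.073), Cst7 to -0.30 (SE 0.10), Apoe to -0.21 (SE 0.046) and Trem2 to -0.28 (SE 0.084). Lpl (0.06), Axl (-0.00), Ctsb (-0.00) and Gpnmb (-0.08) showed no detectable difference, and Spp1 (-0.46, SE 0.23) did not pass.

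The disease-associated score, the mean log2 CPM over the list, was 5.23 ± 0.12 (SD, n = 6) in controls and 5.06 ± 0.046 (SD, n = 7) in knockouts. The difference of -0.17 (SE 0.053) had an exact two-sided permutation p of 0.0076, and 0.14 after adjustment over the 38 lists. Without samples 4301 to 4307 it was -0.11 (exact p = 0.076). All 7 knockouts lay below the control median, and 5 of the 6 controls lay above every knockout. The homeostatic score was 5.26 ± 0.085 (SD, n = 6) and 5.25 ± 0.055 (SD, n = 7), a difference of -0.01 (SE 0.041, exact p = 0.82). Of its 20 genes only Sparc (log2 fold change -0.22), a matrix protein gene also expressed outside microglia, fell when adjusted over the list alone; P2ry12 (0.10), Tmem119 (0.07) and Cx3cr1 (-0.02) did not pass. The disease-associated minus homeostatic score was lower in the knockout by -0.16 (SE 0.033, exact p = 0.0023). Beside these, astrocyte markers were lower by a score difference of -0.06 (SE 0.018, exact p = 0.0029), the oligodendrocyte and myelin score differed by -0.13 (SE 0.064, exact p = 0.071), and the mitochondrial share of counts was lower in the knockout (exact p = 0.0047). Of 26 pan-microglial and myeloid genes 0 passed, with a score difference of -0.04 (SE 0.048, exact p = 0.40).

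The sample numbers in the labels form 3 runs that are unevenly shared by the groups: 5 knockouts and 1 control, 1 knockout and 3 controls, and 1 knockout and 2 controls. Within these runs the disease-associated score differed by -0.10, -0.06 and -0.30, and the disease-associated minus homeostatic score by -0.19, -0.15 and -0.24. When samples were relabelled only within runs, the exact p was 0.056 for the first score and 0.014, the smallest this test can give, for the second. Camera with its preset correlation called the disease-associated list lower (adjusted p = 1.7e-07), but not with an estimated correlation (p = 0.019, adjusted p = 0.41).

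**Figure D2:**
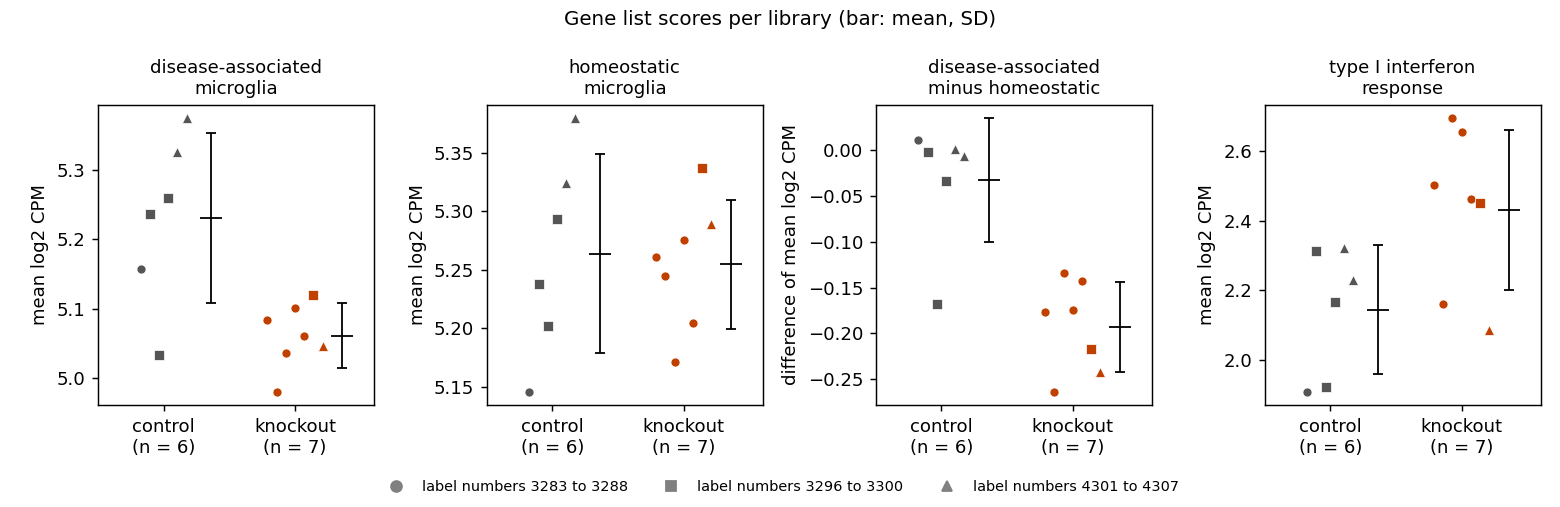
Scores of 3 gene lists, and the difference of 2 of them, in each library (vertical axes, mean log2 CPM or its difference, not starting at 0); symbols give the run of label numbers and the bar the mean with its SD. The disease-associated score averaged 5.23 in controls and 5.06 in knockouts, and the homeostatic score 5.26 and 5.25.

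Type I interferon response genes were higher in most knockouts. Of 31 measured genes, 9 rose when adjusted over the list alone, 0 fell and 22 did not pass; 0 passed over all genes tested and 29 had positive values. They included Gbp3, Oasl2, Ddx58, Ifit2, Ifit1, Ifi44, Usp18 and Stat2. Gbp3, a guanylate-binding protein, rose from 10.1 ± 1.72 to 15.2 ± 3.41 CPM (log2 fold change 0.59, SE 0.15) and Oasl2 from 8.98 ± 1.94 to 13.5 ± 2.7 CPM (0.59, SE 0.15; means ± SD, n = 6 and 7). Isg15 (-0.27) and Cxcl10 (0.19) did not pass. The score was 2.14 ± 0.19 (SD, n = 6) in controls and 2.43 ± 0.23 (SD, n = 7) in knockouts, a difference of 0.29 (SE 0.12, exact p = 0.036, adjusted over the lists 0.30), and 5 of 7 knockouts lay above every control. Its within-run differences were 0.59, 0.32 and -0.19, so the sign turned in the run numbered 4301 to 4307, and the within-run exact p was 0.097; without the samples of that run the difference was 0.40 (exact p = 0.029). With the median over the list in place of the mean the difference was 0.18 (exact p = 0.12). The exact p also exceeded 0.05 without any one of knockout replicates 1, 3, 4, 5 and 6 or control replicates 1 and 3, reaching 0.086. Camera called the list higher with its preset correlation (adjusted p = 1.2e-09) but not with an estimated one (adjusted p = 0.41).

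Other immune lists held few changes. Among 19 antigen presentation genes 0 passed, although camera's preset correlation called the list higher (adjusted p = 0.044; 0.75 with an estimated correlation); H2-D1 was at 0.37, H2-K1 at 0.31 and Cd74 at 0.45. In the complement list 2 of 15 genes fell when adjusted over the list alone, C1qb (-0.23) and C1qc (-0.25), which encode subunits of the initiating complex made by microglia and which did not pass in the pan-microglial list that also holds them (adjusted over that list 0.058), whereas C4b (0.03) did not pass. None of 19 cytokine and NF-kB genes passed. Il1b, with 0 to 13 reads per library, was below the count filter. Genes of border-associated macrophages summed to 14.7 ± 3.23 CPM in controls and 14.7 ± 3.11 CPM in knockouts (SD, n = 6 and 7, exact p = 0.99). The sums were 7.57 and 6.42 CPM for T and NK cells (exact p = 0.11), 27.6 and 23.6 CPM for B cells (exact p = 0.19), 1.07 and 1.92 CPM for neutrophils and monocytes (exact p = 0.065) and 388 and 379 CPM for blood (exact p = 0.60).

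Genes of the arachidonic acid pathway were largely level between the groups. Apart from Lpcat3, 0 of the other 23 phospholipid acyl remodeling genes passed when adjusted over the list alone, including Acsl4 (0.11, SE 0.070), which activates arachidonic acid, and Pla2g4a (0.09, SE 0.13), which releases it. None of 30 arachidonic acid release and eicosanoid genes passed, and the score difference was -0.01 (SE 0.059, exact p = 0.93); Alox5ap was at -0.30 (SE 0.24). In the lipid peroxidation and ferroptosis list 5 of 33 genes fell and 2 rose when adjusted over the list alone. Those that fell were Prdx1, Gpx4, Ftl1, Fth1 and Tfrc. Gpx4, the enzyme that reduces lipid hydroperoxides, fell from 129 ± 7.45 (SD, n = 6) to 107 ± 8.95 CPM (SD, n = 7), a log2 fold change of -0.27 (SE 0.055; adjusted p over all genes 0.096 in edgeR), and of -0.17 (SE 0.057) with the length and GC trends removed. Fth1 and Ftl1 encode the ferritin chains and fell by 0.26 and 0.24 on the log2 scale. Txnrd1 (0.13) and Ptgs2 (0.24), the inducible cyclooxygenase, rose; Ptgs2 passed in this list alone (adjusted over the list 0.047), and not in the eicosanoid (0.30) or the cytokine list (0.095), which also hold it. The list's median (0.01) and mean (-0.03) differed in sign, and its score difference was -0.03 (SE 0.030, exact p = 0.28).

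Lipid synthesis lists did not separate the groups by score. Among 15 LXR target and cholesterol efflux genes only Apoe fell when adjusted over the list alone. Of 24 cholesterol synthesis genes 17 were positive and 0 passed; camera's preset correlation called the list higher (adjusted p = 0.0012), with an adjusted p of 0.63 with an estimated correlation and a score difference of 0.08 (SE 0.066, exact p = 0.23). None passed among 19 fatty acid synthesis genes, 21 unfolded protein response genes, 30 lysosomal genes or 21 App processing genes, with score differences of -0.01 (SE 0.034), 0.04 (SE 0.049), -0.04 (SE 0.051) and 0.01 (SE 0.015).

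Activity-regulated genes of neurons moved both ways. Of 25 activity-regulated genes 7 fell and 2 rose when adjusted over the list alone: Btg2, Fos, Dusp1, Npas4, Ier2, Arc and Sik1 fell, and Nptx2 and Dusp6 rose. Btg2 fell from 53.9 ± 14.7 (SD, n = 6) to 35.9 ± 2.11 CPM (SD, n = 7) and Fos by 0.59 on the log2 scale, whereas Egr1 (0.03) and Nr4a1 (-0.12) did not pass. In the run numbered 3283 to 3288, control replicate 1 had 34.7 CPM of Btg2, inside the knockouts' range of 32.1 to 38.0 CPM. The other controls had 41.8 to 73.3 CPM. The score difference of the activity-regulated list was -0.10 (SE 0.079, exact p = 0.21). Of 16 glucocorticoid response genes 4 rose when adjusted over the list alone, Errfi1 (0.29), Fkbp5 (0.28), Sgk1 (0.54) and Zbtb16 (0.24). Camera called that list higher with its preset correlation (adjusted p = 6.5e-04) but not with an estimated one (adjusted p = 0.48), and its score difference was 0.15 (SE 0.091, exact p = 0.15). Among 16 excitatory neuron genes Neurod2 (0.22) and Neurod1 (0.23) rose and among 20 inhibitory neuron genes Pvalb (-0.33) fell when adjusted over the list alone. The inhibitory list was called lower and the dentate gyrus list (15 genes, 0 passing) higher with the preset correlation (adjusted p = 0.043 and 6.8e-04), with adjusted p of 0.63 and 0.60 with an estimated one. Bhlhe40 (0.35) rose among 16 circadian clock genes, and 0 of 30 synapse, 9 CA1 and 13 CA3 and CA2 genes passed.

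Astrocyte markers had a lower score in the knockout, oligodendrocyte and myelin genes were mostly negative, and vascular lists differed little. Of 21 oligodendrocyte and myelin genes 20 were negative and Opalin (-0.46) alone fell when adjusted over the list alone; the preset correlation called the list lower (adjusted p = 7.1e-04, and 0.63 with an estimated correlation). Astrocyte markers had a score of 7.82 ± 0.033 (SD, n = 6) and 7.75 ± 0.032 (SD, n = 7), a difference of -0.06 (SE 0.018, exact p = 0.0029, adjusted over the lists 0.11), with 0 of 16 genes passing and a camera call (adjusted p = 0.023) that was lost with an estimated correlation (adjusted p = 0.41). Among 18 reactive astrocyte genes Fkbp5 rose when adjusted over the list alone and Gfap (0.07, SE 0.054) did not pass; the preset call of the list (adjusted p = 0.043) was lost with an estimated correlation (adjusted p = 0.63). With the run term, the preset calls of the oligodendrocyte and myelin list (adjusted p = 0.97) and the astrocyte list (0.42) were lost. That of reactive astrocytes was kept (0.033). None passed among 11 oligodendrocyte precursor, 16 endothelial, 12 mural or 15 meningeal fibroblast genes. Choroid plexus and ependymal genes varied widely within both groups, with scores of 3.47 ± 1.46 (SD, n = 6) and 3.02 ± 1.75 (SD, n = 7, exact p = 0.61). Of 13 genes of thalamus and midline structures Zic1 (-1.28, SE 0.33) and Zic4 (-0.79, SE 0.26) fell when adjusted over the list alone, and 0 of 15 neocortical genes passed.

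Mitochondrially encoded transcripts had a lower score in the knockout, and nuclear oxidative phosphorylation and ribosomal protein genes were mostly negative. All 11 mitochondrially encoded transcripts were negative and 9 fell when adjusted over the list alone, among them mt-Nd1 (-0.25) and mt-Cytb (-0.21); the score difference was -0.20 (SE 0.068, exact p = 0.016, adjusted over the lists 0.20). Of 27 nuclear oxidative phosphorylation genes 2 fell when adjusted over the list alone, Sdhb (-0.23) and Ndufv2 (-0.22), and of 37 cytosolic ribosomal protein genes all were negative and 5 fell, among them Rps3 (-0.22) and Rps6 (-0.20). The score differences of these other lists were -0.13 (SE 0.064, exact p = 0.064) and -0.17 (SE 0.081, exact p = 0.055). The preset correlation called these 3 lists lower (adjusted p = 8.0e-08, 9.4e-07 and 2.4e-12), and an estimated correlation none of them (adjusted p = 0.41, 0.41 and 0.48). With the length and GC trends removed the score differences were -0.06 (SE 0.032, exact p = 0.099), -0.06 (SE 0.059, exact p = 0.30) and -0.10 (SE 0.079, exact p = 0.21), and the median exon lengths of the lists were 957, 2101 and 1770 bases against 4039 over all genes tested. The share of counts from mitochondrial genes was 1.78 ± 0.11% (SD, n = 6) in controls and 1.57 ± 0.096% (SD, n = 7) in knockouts (exact p = 0.0047). The share of counts assigned to Lars2, a mitochondrial leucyl-tRNA synthetase gene chosen after its values were seen, was 1.18 ± 0.043% (SD, n = 6) and 1.10 ± 0.025% (SD, n = 7, exact p = 0.0023). Whether these reads stem from Lars2 mRNA was not tested, so the share is not read as expression of the gene. Ribosomal protein genes have many near-identical pseudogene copies, so their counts are uncertain. In all, camera's preset correlation called 13 of 38 lists and an estimated correlation 0, as did fry's test of a shared direction. On scores 0 lists passed after adjustment. Fry's mixed test, which counts changes in either direction, passed for some lists. These were lipid peroxidation and ferroptosis (adjusted p = 0.0013), disease-associated microglia (0.0019), phospholipid acyl remodeling, which holds Lpcat3 (0.020), and activity-regulated genes (0.024). Also passing, each at 0.043, were type I interferon response, LXR targets, pan-microglia and myeloid, fatty acid synthesis and mitochondrially encoded transcripts. Cytokines and NF-kB passed narrowly (0.0498). Passing this test was thus not particular to lists with a score difference, LXR targets having an exact p of 0.92 on scores. The mixed test did not pass for others, such as cytosolic ribosomal proteins (0.076).

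**Figure D3:**
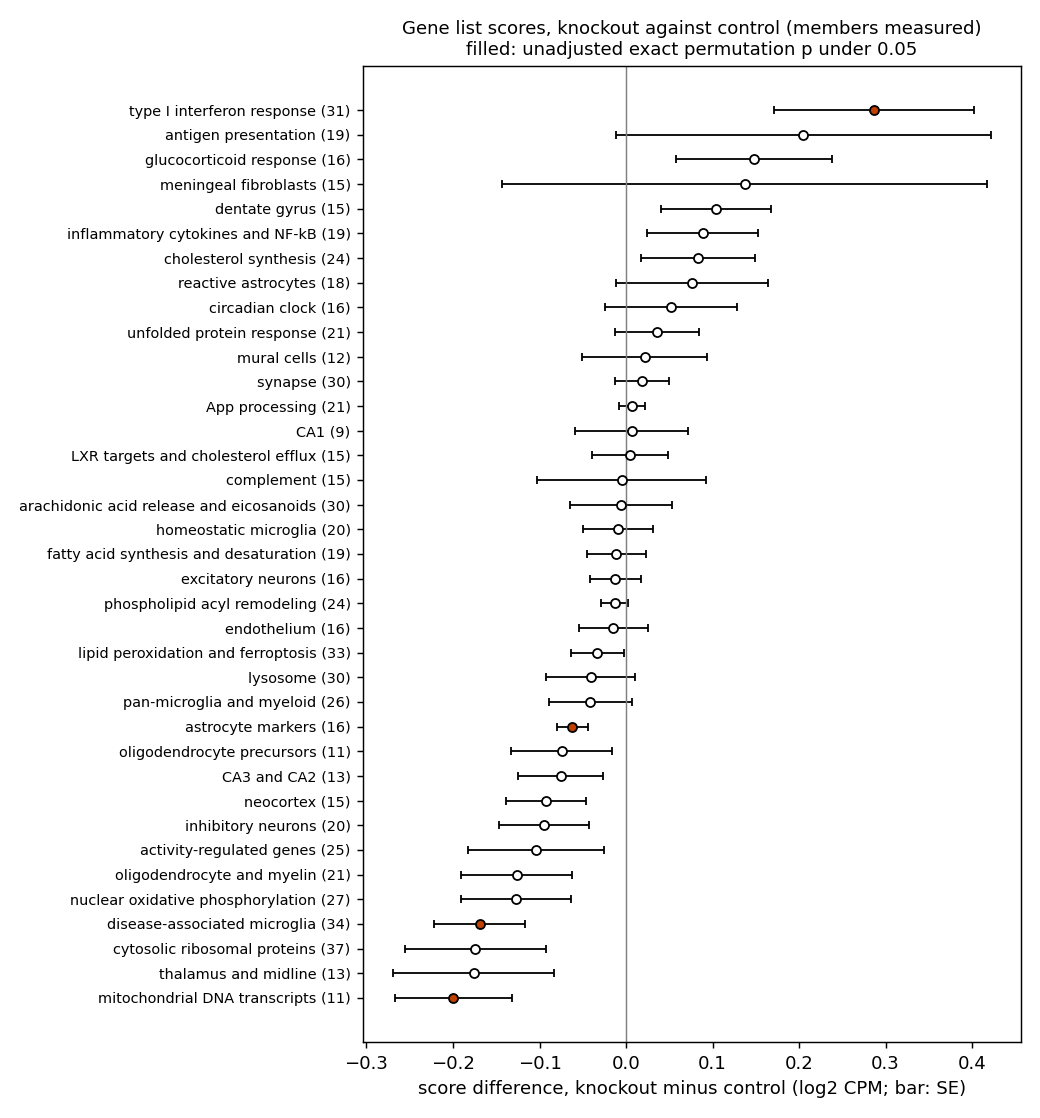
Difference of the mean score between knockout and control (horizontal axis, log2 CPM, with SE) for each gene list tested except choroid plexus and ependyma; the number of measured genes stands in brackets and filled points have an unadjusted exact permutation p under 0.05. Differences ran from -0.20 for mitochondrially encoded transcripts to 0.29 for type I interferon response genes.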

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

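The tests of length and GC trends and the comparison without samples 4301 to 4307 were chosen after the score differences had been seen; for microglial RNA content and number runs the comparisons were fixed before, but the bounds they were held to were set after; the comparisons with matched random lists and with neighbouring genes were set before their results. In each group, libraries far from the rest were sought among 187 group values of named genes, list scores and total counts, and 10 were found where chance gives about 9.35 (1 in 20).

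Knockout replicate 5 stood low for Banp (4.34 log2 CPM, others 4.75 to 5.05), for Bhlhe40 (6.92, others 7.34 to 7.46) and for the circadian clock score (5.86, others 6.05 to 6.13). Knockout replicate 3 stood low for Neurod2 (6.63 log2 CPM, others 6.86 to 6.97) and Neurod1 (5.21, others 5.40 to 5.45). Knockout replicate 4 stood high for nuclear oxidative phosphorylation (score 6.30, others 6.03 to 6.11) and cytosolic ribosomal proteins (5.37, others 4.97 to 5.12). Control replicate 5 stood high for arachidonic acid release and eicosanoids (score 3.82, others 3.49 to 3.55) and for astrocyte markers (7.88, others 7.78 to 7.82). Control replicate 3 stood low for the disease-associated minus homeostatic microglia score (-0.17, others -0.03 to 0.01), inside the range of the knockouts (-0.26 to -0.13).

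Disease-associated microglia genes were lower in the knockout by a score difference of -0.17, and control replicate 3 is the control that runs against this; without it the difference was -0.20. A general loss of short transcripts was argued against by the score difference of -0.13 (exact p = 0.023) with length and GC trends removed. The list's median log2 fold change was -0.18, against -0.02 for the middle of 10000 random lists matched on length and expression. It lay at percentile 0 of these lists, whose 1st percentile was -0.09. That percentile can overstate how rare the value is. Random members were drawn singly, whereas the listed genes vary together (estimated correlation 0.14). Single short members did shrink, Tyrobp from a log2 fold change of -0.46 to -0.26. Less microglial RNA in the tissue was argued against by the disease-associated minus homeostatic score difference of -0.16 (exact p = 0.0023). A difference between the runs of label numbers cannot be told apart from the group for this score, at -0.15 with an exact p of 0.056 within runs, which missed the threshold, although the disease-associated minus homeostatic score differed by -0.19 within runs (exact p = 0.014). A weaker plaque response of Lpcat3-deficient microglia, or an effect of Cre, stays among the open explanations, untested.

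Type I interferon genes were higher in the knockout by a score difference of 0.29. Length and GC trends were argued against by the difference of 0.32 (exact p = 0.023) with both removed, and more microglial RNA by the homeostatic score, whose difference was -0.0090 (SE 0.041). The runs of label numbers cannot be told apart from the group: the difference was 0.27 with an exact p of 0.097 within runs, and knockout replicate 7 lay below both controls of its run. Without that run, samples 4301 to 4307, the difference was 0.40 (exact p = 0.029), so that run did not produce it. An altered interferon state of the knockout tissue therefore remains a hypothesis that could rest on which mice were in which run.

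Gm37068, Sva and Kcp were higher in every knockout library. A change shared by the neighbouring genes, as a large rearranged segment might give, was argued against: 0 of the 30 nearest tested genes (5 on each side of each) had an unadjusted p under 0.01, and their log2 fold changes ran from -0.31 to 0.15. Reads transcribed from the Cre transgene or from its place of insertion, and linked alleles inherited with Cre, were not tested, since the counts hold no sequence.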

How the results depend on the processing

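Trend removal, the septum covariate, leaving out libraries for the type I interferon score and list tests and scores without samples 4301 to 4307 were chosen after seeing the data. The cause of each change below was not tested, except where fewer samples or genes entered. The disease-associated minus homeostatic score kept its direction and a permutation p under 0.05 in every alternative run for it, at -0.19 to -0.14 and, over single left-out libraries, -0.19 to -0.15. The disease-associated score did so too, and over left-out libraries ranged from -0.20 to -0.13, but not when permuted within runs (-0.15, exact p = 0.056) or without samples 4301 to 4307 (-0.11, exact p = 0.076). The homeostatic score difference lay farthest from 0 with the median over the list, at -0.059 (exact p = 0.45). It turned to 0.044 within runs, 0.0115 with the length trend removed, 0.0114 with length and GC trends removed and 0.032 without samples 4301 to 4307. Over left-out libraries it ranged from -0.027 to 0.021. The type I interferon score fell short with the median over the list (0.18, exact p = 0.12) and within runs (0.27, exact p = 0.097), was 0.40 (exact p = 0.029) without samples 4301 to 4307, and ranged from 0.24 to 0.34 over left-out libraries. Lpcat3 was lower in every alternative; its log2 fold change passed over all genes with no count filter (-0.44, adjusted p = 0.015), DESeq2 (-0.44, adjusted p = 0.0020) and the choroid plexus covariate (-0.44, adjusted p = 0.024), and ranged from -0.50 to -0.41 over left-out libraries, with adjusted p of 0.028 to 0.22.

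Genes called higher and lower (3 and 1 in edgeR) were 21 and 45 with no count filter, 1 and 0 at a mean count of 50 or more (Gm37068 and Sva are not tested there), 104 and 100 with DESeq2, 21 and 57 with the choroid plexus covariate, 3 and 2 with robust edgeR, 3 and 3 without samples 4301 to 4307 and with the homeostatic covariate, and 3 and 0 with the run term and with the septum covariate. Over left-out libraries they ranged from 3 to 40 higher and from 0 to 40 lower, both highest without control replicate 1. DESeq2 gave Gm37068, Sva and Kcp no adjusted p, and its 204 calls held 43 of the 52 genes with an adjusted p under 0.1 in edgeR. Camera called 13 lists, 0 with an estimated correlation, 9 with the run term (8 of the 13, and choroid plexus and ependyma) and 18 without samples 4301 to 4307. Fry's test of a shared direction called 0, and camera's count ranged from 10 to 14 over left-out libraries. Cholesterol synthesis turned lower (-1 for direction) with the run term, where it was not called. Named genes that changed sign, none of them called, were Cx3cr1 (0.072 with the run term, 0.0059 with the myelin and 0.011 with the septum covariate), Pla2g4a (-0.0073 with the run term), Spp1 (0.040) and C4b (-0.031) without samples 4301 to 4307, Acsl4 (-0.0035 with the myelin covariate) and Tmem119 (-0.032 with the septum covariate). Of 932 values of 53 named genes under these alternatives, 841 kept direction and side of the threshold, 70 gained a call and 13, all of Meis2, lost one. At this depth a 1.5-fold change was recovered for 64% of simulated genes, so small shifts of microglial genes in whole tissue are often missed.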

Other observations

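The tests in this part were chosen after the results they bear on had been seen. Genes of the medial septum and basal forebrain, which adjoin the hippocampus, varied among the controls. Control replicate 4 held 63 reads of Chat, the acetylcholine-synthesizing enzyme, and 28 of Lhx8, whereas no other library exceeded 7 and 8. Zic1, a transcription factor of midline forebrain, had 304, 196 and 299 reads in control replicates 2, 3 and 4 and between 53 and 105 in the other libraries. Zic1 (log2 fold change -1.28, SE 0.33), Ecel1 (-1.39, SE 0.36) and Slc10a4 (-1.96, SE 0.43) were lower in the knockout with adjusted p of 0.14, 0.14 and 0.097 in edgeR.

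A candidate explanation is septal tissue in some control pieces. The score of 11 other septum markers was highest in control replicates 4 and 2 (2.74 and 2.30), and the knockout minus control difference was -0.39 (SE 0.24) with an exact two-sided permutation p of 0.11, so the group difference was not settled; 7 striatum markers differed by -0.08 (exact p = 0.20). With the septum score as a covariate the Meis2 log2 fold change was -0.31 against -0.37 without it, so most of it stayed although it was no longer called (adjusted p = 0.18 in edgeR). The disease-associated microglia score differed by -0.17 (permutation p = 0.0052) under the same covariate. This p is approximate, since groups were relabelled while the covariate stayed with its library.

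Of 100 splits of the 13 libraries into groups of 7 and 6, 3, the real one included, gave at least its 4 genes. The highest other split gave 247. Gm37068, Sva and Kcp, 3 of the 4 genes, set every knockout apart from every control, so other splits break them up. The count therefore largely restates these genes and does not decide whether chance gave the rest. The splits also did not keep to the runs of label numbers. That split had the largest difference in choroid plexus score of all 100 (4.25 against 2.04 in its 2 groups, and 3.02 against 3.47 in the real ones), which points to a structure of these samples that follows choroid plexus content in part: another split with scores of 2.31 and 4.30 gave 0 genes. For gene lists, 20 of the 100 splits, the real one included, gave at least 13 lists at camera's preset correlation, with up to 19 in another split, so chance is not excluded for that count.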
